A study of Homo sapiens with 8 samples.

How the data were processed

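The series measured ribosome occupancy and RNA abundance in THP-1, a human line of monocytic acute leukaemia cells grown in culture, either with ALKBH5 knocked down or as control. ALKBH5 is an RNA demethylase that removes the methyl group from N6-methyladenosine (m6A). Each of the 4 groups (footprints and input RNA, knockdown and control) held 2 libraries, 8 in all. Groups were taken from the sample titles, where the knockdown is written A5-KD; the genotype label of the control input libraries reads only "input", so their control status rests on the title alone. Per the labels' protocols, ribosome footprints were released from a cell lysate by micrococcal nuclease and purified by size on a gel for small RNA libraries, and part of the lysate was kept as input; the labels call the input polyA RNA and the footprints total RNA. Nothing in the labels says whether the 2 replicates of a group came from separate cultures, so the errors measure only the spread between these samples, which may be technical.

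The measurement used here is 1 deposited table of 9339 genes, 1 comparison over the whole series, with 0 columns of values per library. Its name shows that the authors used riborex, a package that tests translational efficiency (footprint abundance relative to RNA abundance) with a count model, with its DESeq2 engine. Versions of both, and the unit of the values given to the model, are not given in the sources used here. The submitters' processing notes name CASAVA, HISAT2 2.1.0, kallisto and the genome build hg38, without saying which step each served. The mean signal is the column named baseMean per the file headers, by that tool's convention the mean over all libraries of values divided by size factors. The log2 fold change of translational efficiency and its standard error are the authors' own, as is the Wald statistic, a score; both stand in the deposited table. The p-value and adjusted p-value are also the authors', per the file headers. It was checked that the statistic equals the fold change over its standard error, that the p-value is the tail of a normal distribution on both sides, and that the adjusted p is a Benjamini-Hochberg adjustment over the 648 genes that have one. These 648 are exactly the genes with a mean signal of at least 155.3. The table does not state which condition is the reference of the fold change, so every sign below is the deposited sign, and whether a negative value means lower or higher translational efficiency in the knockdown stays unknown.

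Total counts per library are not given in the table, so the depth of each library is unknown here and no interval based on read counts could be made. The mean signal summed to 713523 over all genes, with a median of 11.9 per gene. Errors printed with fold changes are the authors' standard errors from 2 libraries per group.

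From the table the following was computed. Gene names were updated through a table of the assembly GRCh38.p14, from which positions (1-based) and gene types were also taken: 8920 names matched directly, 254 through an older name and 13 as mitochondrial genes. Another 138 names were not matched, and 14 names had been turned into dates by a spreadsheet; both kinds stayed in the tests and are not named. A gene was called at an adjusted p under 0.05. A total of 37 gene lists (pathways, complexes, markers of this and other cell types) were fixed before the data were examined, and the 34 with at least 5 measured members were tested with limma 3.58.1 (cameraPR, R 4.3.3) on the Wald statistic, with the correlation between genes preset at 0.01 and Benjamini-Hochberg adjustment over the lists. That correlation could not be estimated without values per library. Because the spread of the statistic grew with mean signal, each list's mean statistic was also set against 10000 random lists matched on mean signal, in groups of 200 genes (permutation test, two-sided, smallest possible p 0.0002). The group of highest signal held 339 genes, with mean signals from 296.3 to 112772, so the matching there was coarse. The named genes were chosen by a rule fixed before the data were examined: ALKBH5 and its list of related genes; up to 10 called genes per sign with a mean signal of at least 100, ordered by fold change; 4 members of each called list with the smallest p in the list's direction; and 2 members of the other lists described. A gene named outside the rule is said to have been chosen after its values were seen.

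The steps were tested on simulated data. In a simulated translational efficiency comparison with the deposited standard errors, 200 of 648 genes were changed. Of 100 genes changed by 1 log2 unit 79.0% were recovered, and of 100 changed by 2 units 98.0%. Of the calls, 5.35% were unchanged genes, a share that the adjustment itself holds near its threshold. With so many changed genes the adjustment allows larger p-values than with the 10 calls in the deposited values. The recovered shares therefore do not apply to those values and may be lower there. The set test recovered 3 of 3 shifted lists among 34 and called 0 of the others. The simulated shift was larger in size than the mean statistic of most lists called below, so recovery of smaller shifts was not tested. Noise in both simulations was independent between genes and standard normal at every signal. The deposited statistics instead spread more with mean signal and lean negative at high signal. The rate of false list calls in them therefore cannot be judged from this simulation. Alternatives varied the threshold, the adjustment, the filter on mean signal, the centring, the null distribution, the gene type, the preset correlation, the score and the background of the list test. Planned tests of GC content, coding length and m6A motifs near stop codons were not run, since no transcript sequence was used here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.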

Results

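Ribosome footprints and matched input RNA were collected from THP-1 cells, a human monocytic leukaemia line, with ALKBH5 knocked down or as control, with 2 libraries in each of the 4 groups. The comparison asked which mRNAs are translated differently when ALKBH5, the m6A demethylase, is reduced. The readout was the change in translational efficiency, that is, the difference between conditions in footprint abundance relative to input RNA, and 9339 genes had a value. Signal was low for most of them: the mean normalized signal over all libraries had a median of 11.9, with quartiles of 4.60 and 35.3, and 972 genes reached 100. The depth of each library is unknown here. The deposited sign is used throughout, because the reference condition of the fold change is not stated.

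The knocked-down gene and the genes linked to it by the study's topic had too little signal to receive an adjusted p, and none had an unadjusted p under 0.05. ALKBH5 itself (chromosome 17, 18183828 to 18209954) had a mean signal of 4.85 and a log2 fold change of 1.94 ± 2.30 (SE; unadjusted p = 0.40) in the authors' deposited table. This value concerns translational efficiency and does not show the extent of the knockdown, and levels per library were not analysed here. MYB, a transcription factor of blood progenitors, had 0.82 ± 0.75 (unadjusted p = 0.27) in the authors' deposited table, at a mean signal of 35.7. AXL, a receptor tyrosine kinase, had -0.11 ± 0.87 at a mean signal of 72.8, with a 95% interval from -1.81 to 1.60, in the authors' deposited table or computed from its standard error. KDM4C, a histone H3 lysine demethylase, had -0.02 with a 95% interval from -3.95 to 3.90, and the AXL ligand GAS6 had 0.16 ± 1.37, in the authors' deposited table or computed from its standard error. TYRO3, a relative of AXL, had a mean signal of 1.44 and a log2 fold change of -0.44 ± 3.51 in the authors' deposited table. With the deposited errors a change of 1 log2 unit would not reach an unadjusted p of 0.05 in any of them. MYB did not pass with the adjustment over all genes or after centring. It passed only when the statistics were rescaled by their spread over all genes (adjusted p = 0.0035) or among genes of similar signal (adjusted p = 0.037, chosen after seeing the data). The first rescaling passed 354 genes. Both take the deposited errors to be too wide, which was not tested, so MYB is not shown to have changed. As a list of 6 measured genes, 3 negative and 3 positive, this group did not pass the set test (limma cameraPR, adjusted p = 0.18), and 0 members passed when adjusted over the list alone. The list was drawn up from the study's topic and is not independent of it.

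Of the 648 genes with an adjusted p in the authors' deposited table (riborex with the DESeq2 engine), 10 passed an adjusted p of 0.05, all 10 with a negative log2 fold change and 0 with a positive one. MT-ND6, a subunit of respiratory complex I encoded in the mitochondrial genome, had the smallest p, and MTRNR2L12, a nuclear gene resembling part of the mitochondrial 16S ribosomal RNA, was also called. RPL5, RPL38, RPL13A and RPS27 encode proteins of the cytosolic ribosome. TMSB4X encodes thymosin beta 4, which binds actin monomers, FCGR2A a low-affinity Fc receptor of myeloid cells, and ERH a small conserved nuclear protein. The remaining gene was C12orf57.

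In the authors' deposited table, the log2 fold change of MT-ND6 was -1.12 ± 0.16 (SE; adjusted p = 4.7e-09), a ratio of 0.461 between conditions, and that of C12orf57 was -1.17 ± 0.26 (adjusted p = 9.2e-04), a ratio of 0.443. TMSB4X stood at -0.91 ± 0.16 (adjusted p = 3.6e-06) and FCGR2A at -0.80 ± 0.17 (adjusted p = 4.0e-04) in the authors' deposited table. For the ribosomal protein genes the authors' deposited table gave -0.72 ± 0.16 for RPL5 (adjusted p = 7.3e-04), -0.71 ± 0.16 for RPL38 (adjusted p = 9.2e-04), -0.50 ± 0.14 for RPL13A (adjusted p = 0.033) and -0.92 ± 0.27 for RPS27 (adjusted p = 0.045). MTRNR2L12 had -0.43 ± 0.10 (adjusted p = 9.4e-04) and ERH -0.57 ± 0.16 (adjusted p = 0.039) in the authors' deposited table. At an unadjusted p under 0.05, 66 genes passed, 56 negative and 10 positive. RPL13A, ERH and RPS27 did not pass when the adjustment covered all 9339 genes. With the statistics rescaled by their spread over all genes, 354 passed, 266 negative and 88 positive.

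The called genes lie at the following positions in GRCh38.p14, each given as the span of the whole gene. FCGR2A (161505457 to 161524048), RPL5 (92831986 to 92841924) and RPS27 (153990762 to 153992155) are on chromosome 1. MTRNR2L12 is on chromosome 3 (96617186 to 96618223), C12orf57 on chromosome 12 (6943433 to 6946003), ERH on chromosome 14 (69380128 to 69398299), RPL38 on chromosome 17 (74203678 to 74210655) and RPL13A on chromosome 19 (49487608 to 49492308). TMSB4X is on chromosome X (12975110 to 12977223), and MT-ND6 spans bases 14149 to 14673 of the mitochondrial genome. Whether the counting used strand, and how it treated reads shared with copies such as the TMSB4X pseudogenes, is not given in the sources used here. The spans of 4 called genes overlap small RNA genes in the annotation: a tRNA gene in FCGR2A, the U7 snRNA gene RNU7-1 in C12orf57, and snoRNA genes in RPL5 and RPL13A. Pseudogenes named for the gene are annotated for 6 of the 10 (TMSB4X, RPL5, RPL38, RPL13A, ERH and RPS27), and MTRNR2L12 is itself annotated as a pseudogene, so these values are uncertain in that respect. Without the 4 genes that overlap small RNA genes 6 called genes were left, and without those of either kind 1, MT-ND6 (both chosen after seeing the data). Among the 648 genes with an adjusted p, 9.72% overlap a small RNA gene and 54.9% have a named pseudogene. Mitochondrial genes were looked up without their MT prefix (MT-ND6 as ND6), so nuclear copies named with it were not counted. The search for small RNA genes left out the mitochondrial genome. MT-ND6 is thus left by the way the searches were made and is not shown to be free of copies.

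**Figure D1:**
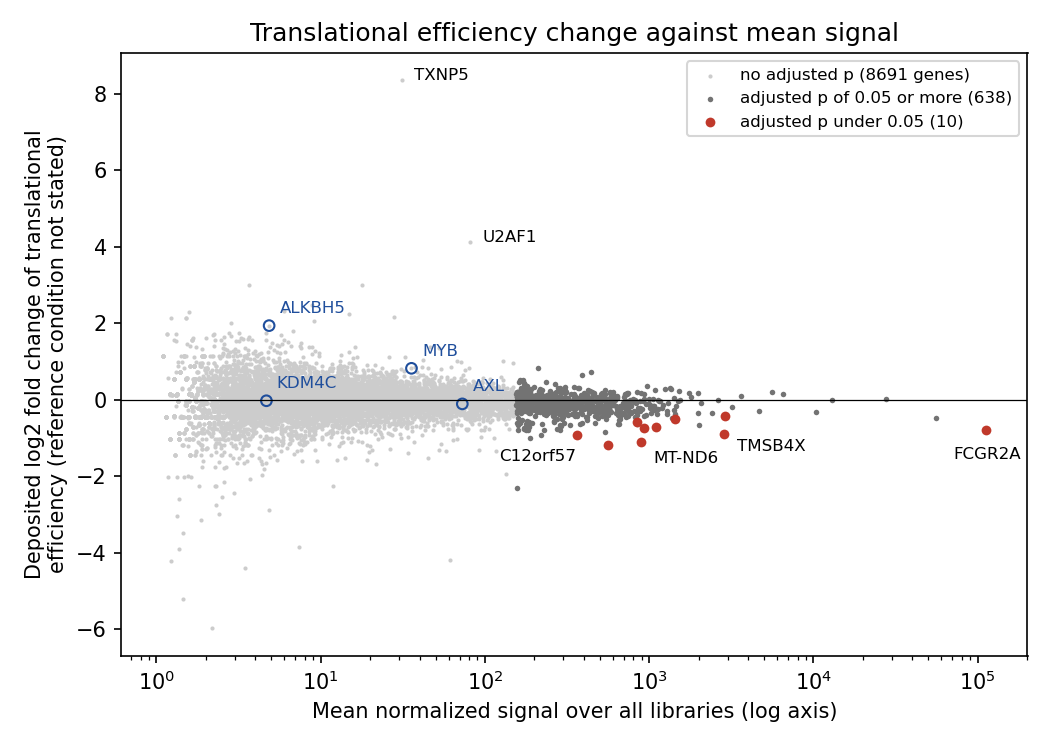
Deposited log2 fold change of translational efficiency of each gene (vertical axis, log2 units) against its mean normalized signal over all libraries (horizontal axis, log scale). Points are genes, red points the 10 with an adjusted p under 0.05, which all lie below 0, and blue circles mark 4 genes of the ALKBH5 list.

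Cytosolic ribosomal proteins and mitochondrially encoded proteins stood on the negative side as groups. Of 79 ribosomal protein genes measured, 73 had a negative and 6 a positive log2 fold change, with a median of -0.24 (quartiles -0.35 and -0.12), a ratio of 0.849. The 4 with the smallest p were the called genes RPL5, RPL38, RPL13A and RPS27, and 5 passed when adjusted over the list alone. Each of these 4 has annotated pseudogenes, from 6 for RPL38 to 35 for RPL5. Reads shared with such copies leave the values of the list uncertain. All 13 mitochondrially encoded protein genes were negative, with a median of -0.33. Of these, 1 gene, MT-ND6, was called over all genes, and 2 passed when adjusted over the list alone. In the authors' deposited table MT-CO3, a subunit of cytochrome c oxidase, had -0.49 ± 0.15 (adjusted p = 0.077), MT-ATP8 of ATP synthase -0.42 ± 0.21 (adjusted p = 0.48) and MT-ND4 of complex I -0.51 ± 0.26 (adjusted p = 0.56). The set test (limma cameraPR) gave an adjusted p of 9.1e-80 for the ribosomal proteins and 8.5e-48 for the mitochondrially encoded proteins. With genes of at least 100 in mean signal alone, the same test gave 6.1e-10 and 2.0e-07. Both lists have high signal, with medians of 519.3 and 779.3. Genes of high signal were mostly negative and their statistics spread more than those of all genes, so each list was also set against random lists matched on signal. These draw genes independently and leave out any correlation between members of a list, so their p may be too small. The medians of both lists lie in the matching group of highest signal, 339 genes from 296.3 to 112772. Within that group signal was not matched further, so an effect of signal on these 2 lists is only partly removed. Against those the permutation test gave an adjusted p of 0.0034 for the ribosomal proteins and 0.0045 for the mitochondrially encoded proteins. With the fold change as score in place of the statistic, the mitochondrially encoded proteins did not pass (limma cameraPR, adjusted p = 0.091).

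Nuclear-encoded oxidative phosphorylation genes, replication-dependent histones and antigen presentation genes also passed the set test on the negative side, but not against lists matched on signal. The matched lists were drawn from all genes of a signal group, the mostly negative ribosomal and mitochondrially encoded protein genes included. Not passing there therefore does not show that signal accounts for a shift. Of 76 oxidative phosphorylation genes, 57 were negative, with a median of -0.13 (limma cameraPR, adjusted p = 2.4e-11, matched permutation test adjusted p = 0.67). In the authors' deposited table COX6A1 had -0.66 ± 0.26, ATP5ME -0.54 ± 0.26, COX4I1 -0.38 ± 0.19 and UQCRB -0.65 ± 0.34, with adjusted p of 0.24, 0.48, 0.48 and 0.56. Of 27 histone genes, whose mRNAs mostly lack a poly(A) tail while the input is labelled polyA RNA, 22 were negative, with a median of -0.36 (limma cameraPR, adjusted p = 0.0016, matched permutation test adjusted p = 0.25). HIST2H4A had -0.64 ± 0.48, HIST1H4C -0.30 ± 0.22, HIST1H2BK -0.60 ± 0.49 and HIST2H2BF -0.75 ± 0.76 in the authors' deposited table. Histone genes of a family are near-identical, and reads shared among them leave these values uncertain. Of 10 antigen presentation genes, 7 were negative, with a median of -0.10 (limma cameraPR, adjusted p = 0.036, matched permutation test adjusted p = 0.33). B2M, the light chain of class I molecules, had -0.29 ± 0.09 (adjusted p = 0.069) in the authors' deposited table and was the 1 member to pass when adjusted over the list alone. CD74 had -0.25 ± 0.29, HLA-B -0.66 ± 1.75 and PSMB10 -0.05 ± 0.30 in the authors' deposited table. In these 3 lists 0 members were called over all genes, and with the fold change as score none of the 3 passed (limma cameraPR, adjusted p = 0.24, 0.091 and 0.95 in the order above). In the rank version antigen presentation did not pass (adjusted p = 0.49), and with genes of at least 100 in mean signal neither oxidative phosphorylation (adjusted p = 0.58) nor the histones (adjusted p = 0.82) did.

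Glycolysis, cell cycle and lysosome genes stood on the positive side, again with 0 members called over all genes and 0 when adjusted over the list alone. Of 20 glycolysis genes, 17 were positive, with a median log2 fold change of 0.17 (quartiles 0.10 and 0.32), a ratio of 1.12. In the authors' deposited table ALDOA (aldolase) had 0.31 ± 0.13, GAPDH 0.37 ± 0.16, ENO1 (enolase) 0.16 ± 0.16 and HK1 (hexokinase) 1.17 ± 1.24. Of 39 cell cycle genes, 28 were positive, with a median of 0.15. CCND3 and CDK6, a cyclin and a kinase of the G1 phase, had 0.56 ± 0.57 and 0.43 ± 0.59 in the authors' deposited table, the centromere histone CENPA 0.95 ± 1.67 and the cyclin CCNE1 1.25 ± 2.20. Of 31 lysosome genes, 22 were positive, with a median of 0.12. The peptidase TPP1 had 0.51 ± 0.43, the protease CTSD 0.34 ± 0.38, the glucosidase GAA 0.66 ± 0.74 and the proton pump subunit ATP6V1B2 0.42 ± 0.53 in the authors' deposited table. The set test (limma cameraPR) gave adjusted p of 9.7e-08 for glycolysis, 0.036 for the cell cycle and 0.036 for the lysosome. Against lists matched on signal, the permutation test gave 0.0034, 0.0051 and 0.014. With the correlation preset at 0.05, the cell cycle and lysosome lists did not pass (both adjusted p = 0.25), nor did antigen presentation (adjusted p = 0.13), while glycolysis and the other 4 called lists did. With the fold change as score glycolysis (adjusted p = 0.24), the cell cycle (adjusted p = 0.15) and the lysosome (adjusted p = 0.54) did not pass. With genes of at least 100 in mean signal, glycolysis passed (adjusted p = 1.5e-04), but the cell cycle, with 5 members left and a median of -0.01, did not (adjusted p = 0.78), nor did the lysosome (adjusted p = 0.19).

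**Figure D2:**
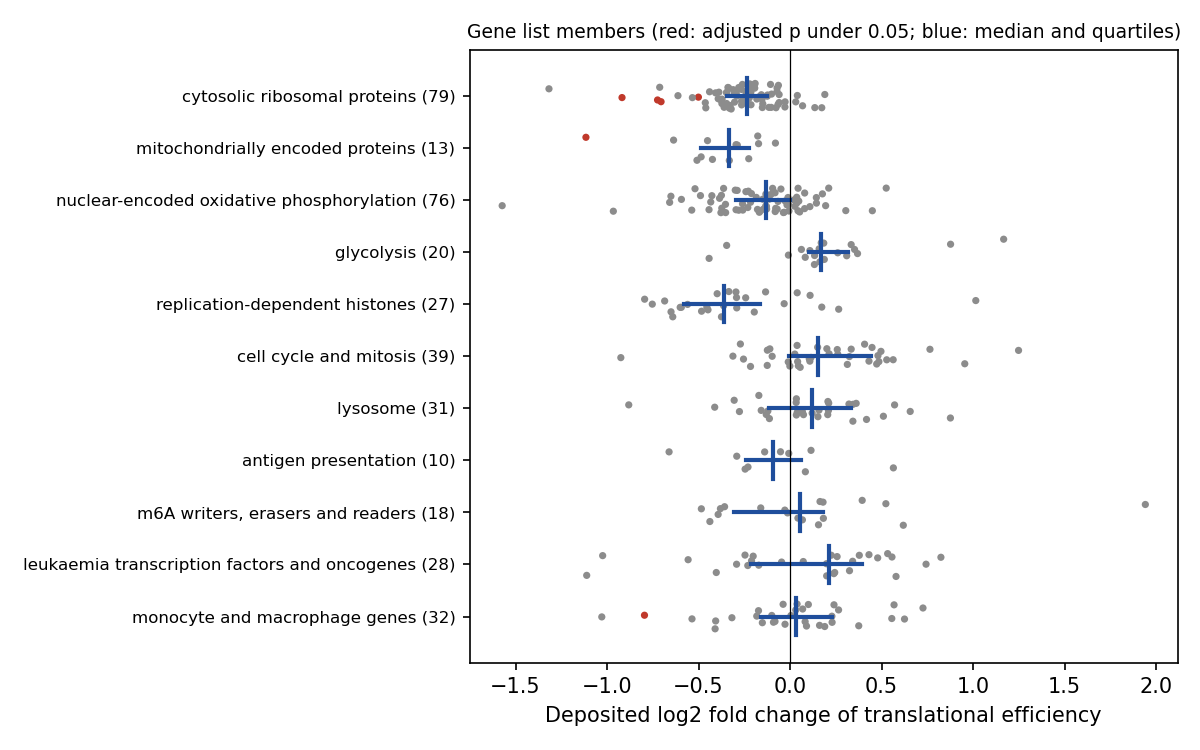
Deposited log2 fold change of translational efficiency (horizontal axis, log2 units) of the measured members of the 8 called gene lists and 3 others (vertical axis, number of members in brackets). Points are genes, red those with an adjusted p under 0.05, blue bars the median and quartiles, and all 13 mitochondrially encoded genes lie below 0.

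The remaining 26 lists tested did not pass the set test. Of 18 measured m6A writers, erasers and readers, 8 were negative and 10 positive, with a median of 0.06 (limma cameraPR, adjusted p = 0.64). The reader HNRNPA2B1 had -0.16 ± 0.18 in the authors' deposited table. Other RNA-modifying enzymes had a median of 0.12 (adjusted p = 0.77), with TRMT112 at -0.40 ± 0.40 and ADAR at 0.65 ± 0.74 in the authors' deposited table. Of 28 leukaemia transcription factors and oncogenes, 17 were positive, with a median of 0.21 (adjusted p = 0.32), and NPM1, a nucleolar protein, had -0.20 ± 0.15 in the authors' deposited table. Of 32 monocyte and macrophage genes, 18 were positive, with a median of 0.03 (adjusted p = 0.32) and a mean statistic below 0. Among these FCGR2A was called, and LYZ, the lysozyme gene, had -0.41 ± 0.13 (adjusted p = 0.084) in the authors' deposited table. Both passed when adjusted over the list alone.

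DNA replication (median 0.12, adjusted p = 0.11) and mitochondrial ribosomal proteins (median -0.13, adjusted p = 0.14) came closest to the threshold of the set test (limma cameraPR). In the authors' deposited table MCM3 had 0.40 ± 0.40, RFC5 0.70 ± 0.94, MRPL21 -0.39 ± 0.42 and MRPL1 -0.59 ± 0.81. The adjusted p was 0.22 for aminoacyl-tRNA synthetases (median 0.09), 0.32 for interferon response genes (median -0.10) and translation factors (median -0.07), 0.41 for cholesterol and fatty acid synthesis (median 0.01), and 0.45 for the proteasome (median -0.05) and the unfolded protein response (median -0.06). It was 0.67 for DNA damage response (median 0.03) and the ATF4 response (median -0.01), 0.77 for autophagy (median 0.04), mRNA decay (median -0.09), the spliceosome (median 0.04), the TCA cycle (median 0.04), cytosolic chaperones (median 0.06) and inflammatory genes (median 0.04), and 0.82 for histone demethylases (median -0.02). It was 0.89 for oxidative stress and iron genes (median 0.02) and ribosome biogenesis (median 0.01), and 0.95 for apoptosis regulators (median 0.04) and the mTORC1 pathway (median -0.10). Markers of other cell types were mostly not measured: 2 of 25 lymphoid, 1 of 22 erythroid and megakaryocyte and 1 of 20 epithelial and fibroblast markers had a value, none with a mean signal over that of NKG7, 15.2. These 3 lists were not tested. The median fold change and the direction of the set test had opposite signs for monocyte and macrophage genes, the spliceosome, cytosolic chaperones, ribosome biogenesis, histone demethylases and the ATF4 response, none of which passed. For apoptosis regulators and oxidative stress genes the mean statistic was negative while the median and the test were positive.

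The share of negative fold changes depended on mean signal. It was 51.9% over all genes (4846 of 9339), 68.4% among the 648 genes with an adjusted p (443 of 648) and 71.4% among the 56 genes with a mean signal of at least 1000 (40 of 56). The median log2 fold change was -0.02 over all genes and -0.12 over the 648. The Wald statistic had an SD of 0.43 over all genes and 1.06 over the 648, against 1 for a standard normal. Among the 56 genes of at least 1000 its SD was 1.85 and its robust spread 1.51. The called genes TMSB4X, FCGR2A, RPL38, MTRNR2L12 and RPL13A lie in that range. Their deposited p-values may be too small, but real changes would also widen the statistic, so this cannot be told apart here. Of the summed mean signal, 27.4% lay in 3 genes, FCGR2A (15.8%), CCNL1 (7.77%) and WDR74 (3.85%), which were chosen after their values were seen.

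**Figure D3:**
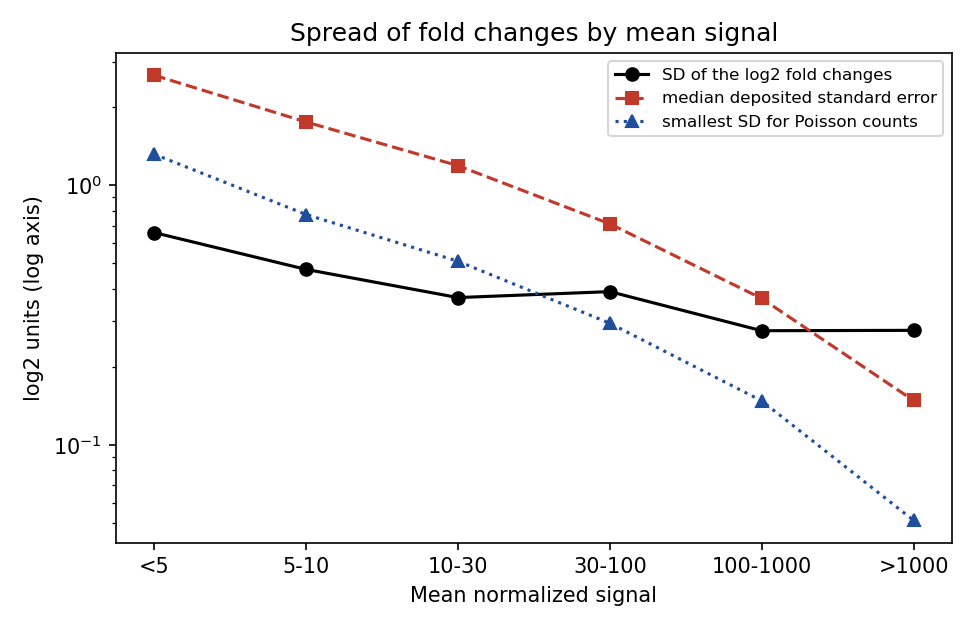
Spread of the log2 fold changes in 6 ranges of mean normalized signal (horizontal axis), in log2 units on a log scale (vertical axis). Black points are the SD of the deposited fold changes, red squares the median deposited standard error and blue triangles the smallest SD that Poisson counts allow; the SD is below the standard error except for the 56 genes of at least 1000.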

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

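Rescaling the statistics among genes of similar signal or over the 648 genes alone, and leaving out genes by name or by annotation, were chosen after seeing the data. The first was limited to genes of at least 10 in mean signal after a version over all genes had given 199 calls (89 negative, 110 positive), 95 of them in the lowest group of 200 genes, where the robust spread was 0.00713. The count of called genes, 10 in the deposited adjustment, was 2 with a log2 fold change of at least 1 in size as a further condition, 6 with protein-coding genes alone, where the adjustment covered 9036 genes, 6 without FCGR2A, MTRNR2L12, TMSB4X and MT-ND6, picked by hand, 6 without genes overlapping a small RNA gene, and 1 without these, pseudogenes and genes with a named pseudogene, the last 3 by construction. It was 354 (266 negative, 88 positive) when the statistics were rescaled by their robust spread over all genes, which is set mostly by genes of low signal, 41 (31 negative, 10 positive; 7 of the 10 kept) with the rescaling among genes of similar signal, and 20 (15 negative, 5 positive; all 10 kept) with it over the 648 genes. In the other 6 alternatives the count lay between 7 and 15. The count of called lists, 8 in the main test, was 5 with the correlation preset at 0.05, 5 against random lists matched on signal, 5 with statistics standardised among genes of similar signal, 3 with genes of at least 100 in mean signal, where 19 lists could be tested, and 1, the ribosomal proteins, with the fold change as score, for which the cause was not tested. It was 10 with the correlation at 0 and 8 in the rank version, where mitochondrial ribosomal proteins passed (adjusted p = 0.0022) and antigen presentation did not. The same 5 lists (ribosomal proteins, mitochondrially encoded proteins, glycolysis, cell cycle and lysosome) passed against matched lists and among genes of similar signal. Both alternatives use the same statistic and signal groups formed in the same way, so their agreement is not independent support. The direction of the set test against other genes stayed the same for the 8 called lists in the alternatives that could test them, but the median of the cell cycle list was -0.01 with genes of at least 100 in mean signal. After centring, FTL turned from -0.0021 in the authors' deposited table to 0.0168. No paired analysis was possible because the table holds no values per library, and for the same reason the fits with each replicate left out were not run. The median standard error was 0.29 log2 units over the 648 genes and 1.38 over all genes, and how much of it comes from depth is unknown.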

Other observations

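The tests of scaled values and of shrinkage below, and the rescaling among genes of similar signal, were chosen after the result was seen; the test of structural RNA genes was prompted by the names of the genes with most signal, before their overlaps were looked up. The genes named in this paragraph were chosen after their values were seen. On the positive side, the authors' deposited table gave ZMPSTE24, a protease that matures lamin A, a log2 fold change of 0.73 ± 0.24 (SE, adjusted p = 0.084) and LCP1, the actin-bundling protein plastin of leukocytes, 0.66 ± 0.27 (adjusted p = 0.27). CAP1, which binds actin, and ACTB, beta-actin, had 0.20 ± 0.08 and 0.16 ± 0.08 in the authors' deposited table (adjusted p = 0.24 and 0.44). The largest fold change in the authors' deposited table was that of the pseudogene TXNP5, 8.36 ± 2.20 (unadjusted p = 1.5e-04), and the splicing factor U2AF1 had 4.13 ± 1.61 (unadjusted p = 0.010). Neither had an adjusted p, at mean signals of 31.1 and 80.8, and both share sequence with other genes, which leaves their values uncertain.

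A few genes held much of the signal, and structural RNA genes inside them are a candidate source. Of the 10 genes with the largest mean signal, 3 overlapped a tRNA, snRNA or similar gene in GRCh38.p14, against a mean of 0.234 in lists matched on gene span (one-sided permutation p = 0.0013). FCGR2A overlaps a glycine tRNA gene, WDR74 the U2 snRNA gene RNU2-2, and CTC1 (1.45% of the signal) 3 tRNA genes. The 15.8% of the signal in FCGR2A, and its call, may therefore come in part from RNA fragments of footprint size that are not footprints of its mRNA. CCNL1 (7.77%) and FTL (1.82%) overlapped none, which leaves them unexplained (both, like WDR74 and CTC1, chosen after their values were seen), and how reads were assigned was not tested.

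At a mean signal from 10 to 30 the Wald statistic had an SD of 0.304, narrower than a standard normal. Wide errors are part of this: the median deposited standard error there was 1.19, against a smallest SD for Poisson counts of 0.510. Why the errors are wide was not tested, and the next values concern the fold changes alone. Among the 2480 genes with a mean signal from 10 to 30, the SD of the log2 fold change was 0.724 times the smallest SD that Poisson counts of that mean allow in this design (95% bootstrap interval 0.691 to 0.763), which is consistent with values scaled to a common total, such as TPM, having entered the model in place of read counts. From 30 to 100 the ratio was 1.32 with the SD but 0.891 with a robust spread, which outlying genes such as TXNP5 and U2AF1 do not carry, and it was 1.86 from 100 to 1000 and 5.39 at 1000 and over, which counts also allow. Shrinkage by a normal prior is argued against, since the largest standard error, 4.28, would bound the prior and leave at least 0.923 of a fold change at the median error of the genes from 10 to 30. Rescaled among genes of similar signal, 41 genes passed in place of 10, among them the named genes TXNP5 (adjusted p = 1.7e-26), U2AF1 (1.0e-05), IFITM2 (0.0081, negative), HK1 (0.035) and MYB (0.037; from 0.0035 to 1 over its alternatives), while RPL13A, ERH and RPS27 did not.

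For the 10 called genes, no technical explanation weighed here was excluded. Low read counts stayed open: the median mean signal of the called genes was 3.32 times that of the 648 genes with an adjusted p, but the standard error fell with mean signal across these genes (Spearman's rho = -0.841), so calls favour high signal in any case. Reads shared with pseudogene copies stayed open, since 1 of the 10, against a mean of 0.342 in random lists, had a pseudogene of its own name in the table (one-sided permutation p = 0.30). Poly(A) selection of the input RNA but not of the footprints stayed open too: 0 of the 7 histone genes with an adjusted p were called, but with 10 of 648 genes called in all, 7 are too few to show a lower share. Only histones were tested, and whether the mRNAs of the 10 called genes, MT-ND6 among them, carry a poly(A) tail was not looked up. Coding length, GC content and m6A motifs were not tested here, and neither was a biological explanation, because the direction of the fold change and the values per library are not known here.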
